A study of Hyaloscypha hepaticicola with 6 samples.

How the data were processed

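RNA sequencing libraries of the ericoid mycorrhizal fungus Rhizoscyphus ericae UMAH 7357, listed in the labels under the name Hyaloscypha hepaticicola, were compared between 2 conditions. Per the labels' protocols, the free-living mycelium grew on cellophane over a modified MMN agar with bovine serum albumin, and the mycorrhizal roots came from Vaccinium myrtillus (bilberry) seedlings inoculated with the fungus on the same medium. Both were collected at day 75. The labels name 3 biological replicates per condition. Per the labels' protocols, the plates of mycelium were grown to give material for 3 RNA extractions, so the replicates of that condition are extractions whose plates may have been combined, and p-values measure the spread between these libraries. RNA was extracted with a Tris and phenol procedure from mycelium and with a CTAB procedure from roots, per the labels' protocols, so that extraction chemistry and condition coincide. Control plants without the fungus are mentioned in the protocol and were not analysed here.

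Each library came as 1 deposited table of 16784 gene models of the JGI Rhier1 gene set, named by protein ID, with 3 measurements per gene, per the file headers. The first is the deposited count of unique gene reads, the reads that fall on that gene alone. The second is the deposited count of total gene reads, never lower than the unique count. The third is the RPKM calculated by the authors. Dividing total gene reads by RPKM and by the library's sum gave the same gene length in all 6 libraries, whole to within 0.0003 bp, so the deposited RPKM values rest on the total reads and the sum over genes. Lengths were recovered in this way for 16636 gene models (median 1266 bp) and not for the other 148, which had no reads. The reads were 150 bp long and from an Illumina HiSeq2500, per the series design text. The aligner, the counting tool, their settings, the genome build and the strandedness are not given in the sources used here.

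Unique gene reads were used for the comparison, because reads shared between near-identical copies are left out of them. They summed to between 86008370 and 98560657 per library in mycelium and to between 17465257 and 33420275 in roots. A count of 3 reads, taken as the floor of detection, corresponded to 0.0304 to 0.0349 CPM (counts scaled to library size) in the mycelium libraries and to 0.0898 to 0.172 in the root libraries. Intervals and floors of this kind cover counting error only. Replicate libraries differed from each other by far more than sampling noise (chi-square per degree of freedom of at least 122 in each of the 6 pairs), so none was counted as a repeat sequencing of the same library. This does not show that they came from separate cultures or plants.

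The main test was edgeR 4.0.16 in R 4.3.3: filterByExpr with its default minimum count of 10, TMM normalisation, and the quasi-likelihood F test of mycorrhizal roots against mycelium, two-sided, with condition as the only term and all 6 libraries. p-values were adjusted by the Benjamini-Hochberg method over the 15185 genes tested, with a threshold of 0.05. Changes of at least 5-fold in the fitted value were counted separately. CPM values below are TMM-normalised and not divided by gene length. Abundance and ranks below rest on reads or CPM unless stated otherwise. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. The fitted fold change of a gene with no reads in a condition depends on edgeR's prior count, so a bound is given for such genes against a floor of 3 reads over the 3 mycelium libraries (0.0113 CPM). Genes detected per library (at least 10 reads) and the share of reads in the most abundant genes were compared with exact permutation tests, two-sided, in scipy 1.17.1, for which 3 libraries against 3 allow no p below 0.1.

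The genes named in the text follow a rule set before the data were examined, as were the tests and the first set of alternatives below: with no gene names for the identifiers, the 2 genes with the largest fitted rise and the 2 with the largest fitted fall, among genes past the threshold whose libraries did not overlap between conditions and whose mean was at least 10 CPM in the higher condition. The choice of unique rather than total gene reads as input to the tests was not set beforehand and was made at analysis. The deposited tables do not pair the protein IDs with gene names or functions. The planned lists of functional groups (cell wall degradation, transporters, secreted and surface proteins, secondary metabolism and others, and plant genes as a check), and the lists defined by protein sequence, could therefore not be formed. Other genes are described by abundance, length and direction, without their identifiers.

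On simulated data drawn from the abundances, dispersions and depths of the 15185 tested genes for roots against mycelium, with 200 genes changed, the test recovered 93% of 100 genes changed 5-fold and 26% of 100 genes changed 2-fold, and 7.75% of its calls were false. The adjusted threshold depends on the share of genes changed, and 5618 genes were called in the data. These rates therefore hold for the simulated setting only. With no gene changed, edgeR's quasi-likelihood test called 0 genes (731 at an unadjusted p under 0.05).

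Alternatives chosen beforehand were DESeq2 size factors, upper-quartile factors and total-count scaling in edgeR, no filter and a filter of 5 CPM in 3 libraries, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma 3.58.1 on voom values, tests against a fold of 2 or 5, counts thinned to the shallowest library, and limma-trend on log2(RPKM + 1) of the deposited RPKM values. Alternatives chosen after seeing the data were total gene reads, leaving out the 10 most abundant genes, leaving out genes with 5% or more shared reads, and removing a trend with gene length. No label ties libraries of the same replicate number together. The deviations of same-numbered libraries from their condition means correlated at 0.00 to 0.11, above 0.1 in 1 of the 3 pairs. Libraries of different numbers gave -0.19 to 0.13, and so few values cannot exclude a pairing.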

Results

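The transcriptome of Rhizoscyphus ericae UMAH 7357, an ascomycete that forms ericoid mycorrhiza with heath plants, was measured by RNA sequencing in roots of Vaccinium myrtillus colonised by the fungus (3 libraries) and in free-living mycelium on the same medium (3 libraries). The question stated by the study's title is which fungal genes change in expression between the mycorrhizal roots and the free-living mycelium. Reads assigned uniquely to the 16784 fungal gene models numbered 90025318, 98560657 and 86008370 in mycelium replicates 1 to 3, and 32853402, 33420275 and 17465257 in root replicates 1 to 3. The mycelium libraries were thus 3.28 times deeper on average, and 157 gene models had no unique reads in any library.

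The libraries separated by condition. The first principal component of log2 CPM held 75.3% of the variance and placed all 3 mycelium libraries on one side and all 3 root libraries on the other. Pearson correlations across genes of log2 CPM were 0.98 to 0.99 between mycelium libraries, 0.96 to 0.97 between root libraries and 0.88 to 0.90 between libraries of different conditions. Genes are not independent replicates, so these values carry no test. The biological coefficient of variation, as edgeR names it, fitted to the tested genes was 0.228 within mycelium and 0.288 within roots. The mycelium replicates may be extractions from combined plates, so these values may not measure the same kind of spread.

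A large part of the expressed fungal genes, 37.0% of those tested, differed between the conditions. Of 15185 genes tested, 2960 were higher in mycorrhizal roots and 2658 were lower, and 9567 did not pass the test (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median log2 fold change was 1.29 among the genes that rose and -1.05 among those that fell. The values of the 3 root libraries lay entirely outside those of the 3 mycelium libraries for 52.3% of all tested genes, where chance gives 10%. The count rested in part on mycelium replicate 1: without it 3663 genes passed, of which 1611 were lower in roots. Of the 5618 called genes, 3623 to 4723 remained called when 1 of the 6 libraries was left out.

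Large changes were mostly increases in the roots. At least 5-fold higher in roots were 670 genes, against 261 at least 5-fold lower, and at a threshold of 10-fold the numbers were 358 and 97. Increases therefore made up 52.7% of all called changes, 72.0% of those of at least 5-fold and 78.7% of those of at least 10-fold. The balance among all called changes moved with the scaling more than that among the large ones: total counts instead of TMM, which moved the median log2 fold change of all genes by 0.10, gave 3198 increases and 1981 decreases (61.7% increases) and 75.7% increases among the 5-fold changes, and upper-quartile factors gave 50.5% and 70.8%. When the test itself was made against a fold of 5 (edgeR's glmTreat, adjusted p under 0.05), 306 genes were higher and 63 lower.

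**Figure D1:**
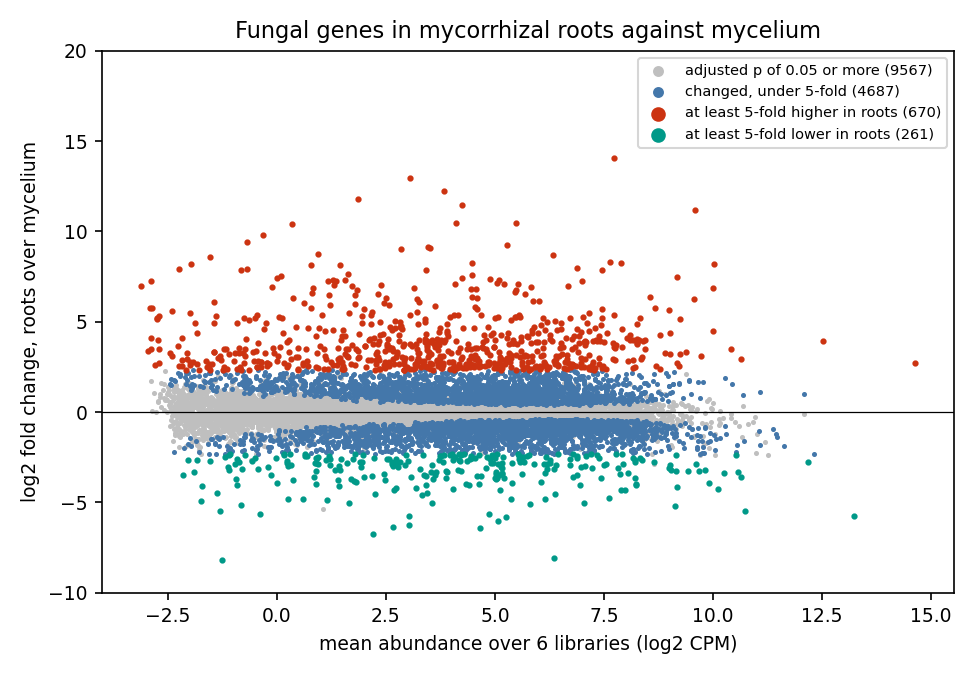
Log2 fold change of each tested fungal gene (mycorrhizal roots over mycelium, vertical axis) against its mean abundance over the 6 libraries (log2 CPM, horizontal axis), 1 point per gene, coloured by the edgeR call. Above the line at 0 lie 670 genes at least 5-fold higher in roots and below it 261 at least 5-fold lower, across the whole range of abundance.

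Genes with large changes were for the most part weakly expressed in the condition where they were lower. The 670 genes at least 5-fold higher in roots had a median abundance of 1.73 CPM in mycelium and 24.3 CPM in roots, and 277 of them were under 1 CPM in mycelium. In the roots, 175 of the 670 reached at least 100 CPM. Together these genes took 14.0% ± 2.63 of the unique reads of the root libraries (SD, n = 3) and 1.35% ± 0.106 of those of the mycelium libraries (SD, n = 3). The 261 genes at least 5-fold lower in roots had a median of 30.8 CPM in mycelium and 3.27 CPM in roots, and 90 of them were under 1 CPM in roots. They took 7.40% ± 1.44 of the mycelium reads and 0.708% ± 0.114 of the root reads (SD, n = 3 each). Both sets were chosen by their change in these libraries, which favours low values in the lower condition of each set. The medians therefore describe the sets, the shares describe their weight in the transcriptome, and neither is a test.

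The genes with the largest fitted changes among those that met the naming rule went from near absence of reads to substantial counts, or the reverse. For those that rose, plant reads counted on fungal gene models cannot be told apart from fungal expression, because libraries of uninoculated roots were not analysed here. Protein ID 721864 (gene model length 1788 bp) rose from 0.0221 ± 0.0383 CPM in mycelium, where its 6 unique reads all came from replicate 3, to 427.1 ± 119.8 CPM in roots (SD, n = 3 each). Its log2 fold change was 14.08 with a standard error of 0.75 (edgeR adjusted p = 2.38e-05). Without mycelium replicate 3 the fitted value was 17.47, since the gene then had no mycelium reads and the fit depends on the prior count. Protein ID 546461 (423 bp) had no unique read in mycelium and 17.0 ± 11.9 CPM in roots (SD, n = 3), at least 1501-fold higher against a floor of 3 reads over the mycelium libraries (edgeR adjusted p = 0.00195). Its fitted log2 fold change of 12.96 depends on the prior count, and 3 other genes that met the same conditions had fitted values above this bound (11.20 to 12.25), so its place as second holds only for the fit. Its root values were uneven, at 25.4, 3.36 and 22.2 CPM in replicates 1 to 3. Protein ID 415105 (780 bp) fell from 162.3 ± 84.6 CPM in mycelium to 0.557 ± 0.350 CPM in roots (SD, n = 3 each), a log2 fold change of -8.09 with a standard error of 0.59 (edgeR adjusted p = 8.51e-05). Protein ID 704713 (1080 bp) fell from 49.3 ± 35.9 to 0.564 ± 0.322 CPM (SD, n = 3 each), a log2 fold change of -6.44 with a standard error of 0.81 (edgeR adjusted p = 9.44e-04). Without root replicate 2 the log2 fold change was 13.55 for 546461 and -8.81 for 415105, and without mycelium replicate 3 it was -5.74 for 704713. The tables give neither names, functions nor genomic positions for these 4 proteins. None of the 4 lost its call under any alternative that tested it, apart from glmTreat, under which single genes were not looked up.

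The gene with the most reads in each condition, by mean CPM not divided by gene length, changed as well. The gene with the most reads in mycelium (1923 bp) stood at 18992 ± 3365 CPM there and at 355 ± 160.0 CPM in roots (SD, n = 3 each), a 53.6-fold fall that took it from the first rank to rank 315 (log2 fold change -5.74, standard error 0.51, edgeR adjusted p = 1.87e-04). The gene with the most reads in roots (918 bp) stood at 44285 ± 20959 CPM there and at 6740 ± 1212 CPM in mycelium, where it already stood at rank 4 (log2 fold change 2.72, standard error 0.49, edgeR adjusted p = 0.00476). It took 3.74%, 3.03% and 6.87% of the unique reads of root replicates 1 to 3. The gene ranked second in roots (500 bp) rose 15.1-fold, from 727.9 ± 82.4 to 10967 ± 4724 CPM (SD, n = 3 each, edgeR adjusted p = 4.41e-04). The gene at rank 4 in roots did not pass the test, with 4483 ± 903 CPM in mycelium and 4190 ± 203 CPM in roots (SD, n = 3 each, edgeR adjusted p = 0.81).

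**Figure D2:**
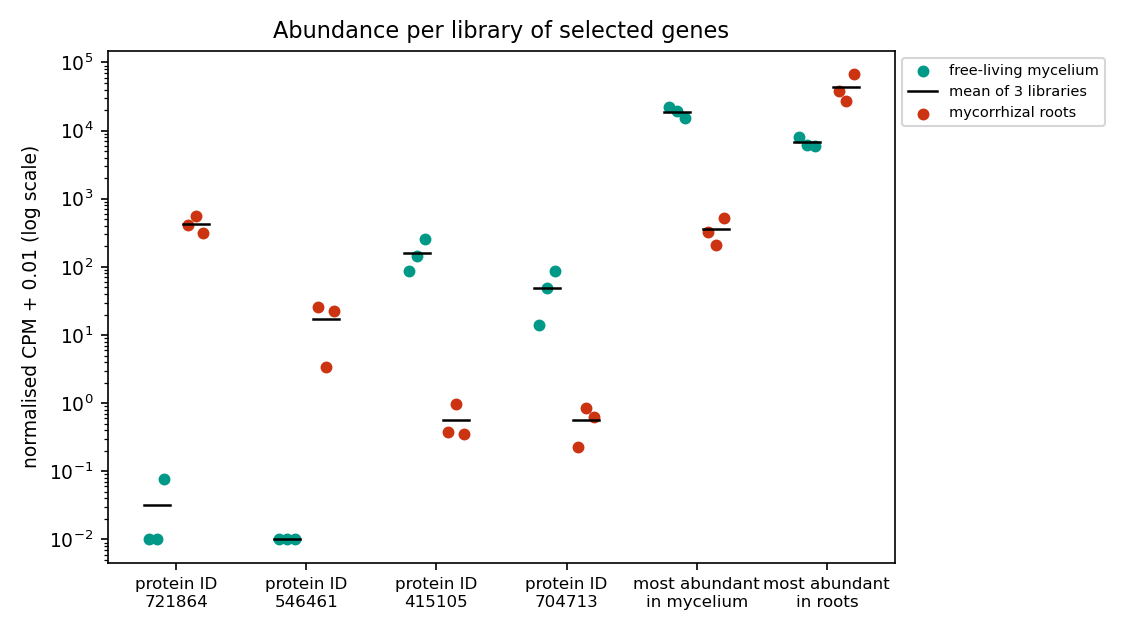
Normalised CPM plus 0.01 on a log axis for 6 genes. By protein ID are the 2 with the largest fitted rise and the 2 with the largest fitted fall among genes that met the naming rule. The other 2 are the genes of highest mean CPM in each condition, not divided by gene length. Each point is 1 library (3 of mycelium, 3 of roots) and each bar the mean of 3; the conditions do not overlap for any of the 6, and points at 0.01 are libraries with 0 unique reads.

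Very few genes were detected in a single condition. With at least 10 unique reads in each library of one condition and none in any library of the other, 6 genes were detected in roots only, with 10 to 816 reads per library and means of 0.809 to 17.0 CPM, and all 6 passed the test. Whether plant reads contributed to the counts of these 6 genes was not tested. In mycelium only, 3 genes were detected, with 10 to 97 reads per library, of which 1 was abundant enough to be tested and passed. These numbers are small against the 670 and 261 genes changed at least 5-fold, and they moved with the minimum: at 1 read or more they were 36 and 35. Leaving out mycelium replicate 3 gave 10 genes in roots only, and leaving out root replicate 1, 2 or 3 gave 11, 10 or 5 in mycelium only.

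Fewer fungal genes were detected in the shallower root libraries. At least 10 reads were found for 14512 ± 392 genes in roots and 15208 ± 107 genes in mycelium (SD, n = 3 each), a difference of -697 genes in roots (exact permutation test, two-sided, p = 0.1, the smallest possible). After thinning all libraries to the 17465257 reads of the shallowest, the order turned, with 14164 ± 142 genes in roots and 13946 ± 215 in mycelium (exact permutation test, two-sided, p = 0.3, n = 3 each). The difference moved with the minimum at full depth too, to -94 genes at 1 read or more (p = 0.7) and -1122 at 50 or more (p = 0.1; exact permutation tests, two-sided, n = 3 each). A difference in the number of expressed genes was not detectable at the depth of the shallowest library.

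The share of reads held by the most abundant genes separated the conditions for the single most abundant gene and for the top 1000, and not for the top 10 or the top 100. The 10 most abundant genes of each library held 8.37% ± 2.66 of the unique reads in roots and 6.95% ± 1.11 in mycelium (SD, n = 3 each, exact permutation test, two-sided, p = 0.6). This order rested on root replicate 3, where the share was 11.4%: without it the difference of 1.42 percentage points was -0.11, and it was 0.78 without mycelium replicate 3 and 2.36 without root replicate 2. With counts divided by gene length it was 3.91 percentage points (exact permutation test, two-sided, p = 0.5, n = 3 each). The 100 most abundant genes held 18.6% ± 2.41 in roots and 20.4% ± 2.28 in mycelium (exact permutation test, two-sided, p = 0.5, n = 3 each). The difference of -1.88 percentage points was -0.74 without mycelium replicate 1, -3.02 without mycelium replicate 3, -0.72 without root replicate 2 and -3.12 without root replicate 3, and with counts divided by gene length it turned to 1.29 (exact permutation test, two-sided, p = 0.8, n = 3 each). The single most abundant gene held 4.55% ± 2.05 in roots and 1.82% ± 0.196 in mycelium, with no overlap between the conditions (exact permutation test, two-sided, p = 0.1, the smallest possible with n = 3 each). The 1000 most abundant genes held less in every root library (47.8%, 44.1% and 47.2%) than in any mycelium library (52.8%, 49.7% and 48.2%), with means of 46.4% and 50.2% (exact permutation test, two-sided, p = 0.1, the smallest possible with n = 3 each).

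Changes were spread over the range of abundance, with a different balance at the top. In the quartile of lowest mean abundance over the 6 libraries (up to 5.21 CPM), 635 genes rose and 409 fell. In the second quartile 855 rose and 605 fell, and in the third 769 rose and 629 fell. In the most abundant quartile (69.0 CPM and above) the balance was the other way, with 701 genes higher and 1015 lower in roots, and a median log2 fold change of -0.17. Among changes of at least 5-fold, increases were still the more frequent there, with 151 genes against 70. CPM is not divided by gene length, and whether this pattern is separate from that of gene length below was not tested.

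Among the longest gene models more genes fell than rose, and among the shortest more rose than fell. In the quartile of longest gene models (1978 bp and above), 502 genes rose and 951 fell, with a median log2 fold change of -0.19 (interquartile range -0.57 to 0.27). In the shortest quartile (up to 872 bp), 768 rose and 468 fell, with a median of 0.10 (interquartile range -0.46 to 0.65). Spearman's rho across genes between length and log2 fold change was -0.12 over all tested genes and -0.07 over those that did not pass the test. Between single libraries, rho of length with the log2 difference was -0.17 to -0.03 over the 9 pairs of a root and a mycelium library and reached 0.14 in absolute size between replicates of 1 condition. The trend between conditions thus overlapped in size with that between replicate libraries.

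**Figure D3:**
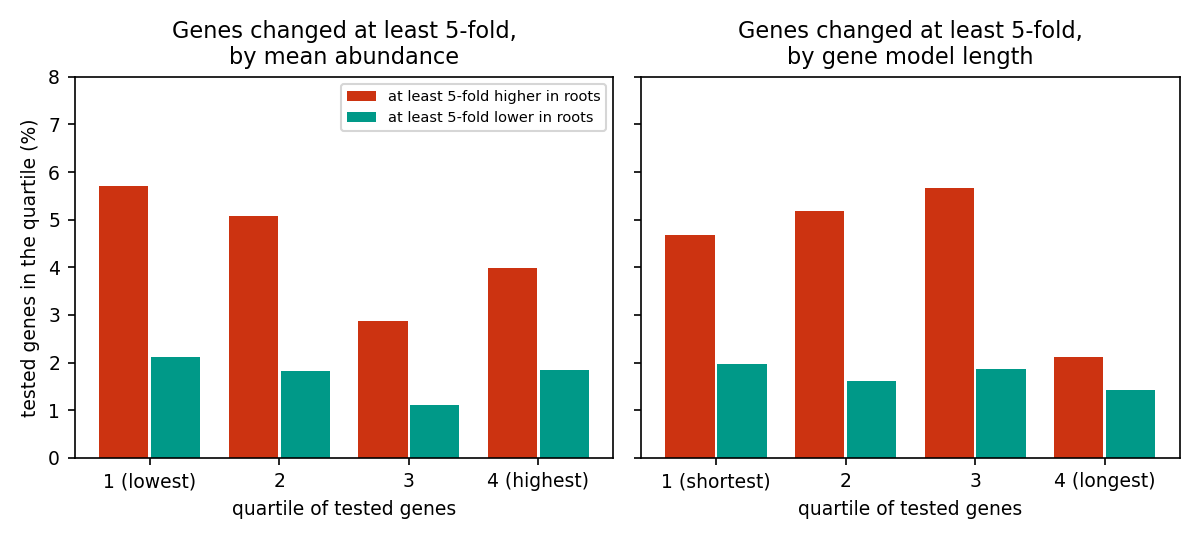
Percentage of tested genes that were at least 5-fold higher (red) or lower (green) in mycorrhizal roots, by quartile of mean abundance over the 6 libraries (left) and of gene model length (right). Increases outnumber decreases in every quartile, from 5.72% against 2.11% in the least abundant quartile to 2.11% against 1.42% among the longest genes.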

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

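The tests in this part were all chosen after the result was seen. The comparison above used unique reads. In the reads left out of it, those counted for a gene in the total but not among its unique reads, the root libraries stood apart. The number of genes with exactly 1 such shared read was 1406, 1581 and 1490 in root replicates 1 to 3, a mean of 1492 ± 87.5, against 341 ± 66.5 in mycelium (SD, n = 3 each, exact permutation test, two-sided, p = 0.1, the smallest possible), although the mycelium libraries were deeper. Genes with more than 10 shared reads numbered 617 ± 71.3 in roots and 784 ± 19.5 in mycelium, and 526 ± 12.6 and 463 ± 28.7 after thinning to the shallowest library, so that order rested on depth. Shared reads made up 0.331% to 0.416% of all gene reads in the 6 libraries.

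Depth argued the other way: with shared reads thinned to the shallowest library, roots still had 5.81 times as many such genes. Fragments joined at random would make the chance of a shared read rise with abundance, with a log-log slope of at least 0.748 in 20 simulations for each root library, drawn over the genes of its own fit (13406, 13538 and 12960 in replicates 1 to 3). The observed slopes were 0.270, 0.334 and 0.283 in root replicates 1 to 3. In mycelium replicates 1 to 3 they were 0.202, 0.303 and 0.231, so slopes of this size were not particular to the root libraries. The simulations took joining as the only source of single shared reads, so they cannot decide on joining on top of another source. In the highest decile of unique reads, 15.1%, 18.8% and 15.8% of genes had exactly 1 shared read in root replicates 1 to 3. In mycelium replicates 1 to 3 it was 3.63%, 5.84% and 3.63%. In the lowest decile it was 0.655% to 1.43% in roots and 0.893% to 0.953% in mycelium. Reads of another organism, such as the plant, or of sequences outside the gene set may contribute. The same genes recurred between root libraries at 1.73 to 1.86 times the chance rate, but recurrence of abundant genes would do the same, and this explanation cannot be told apart from others without the reads. A change in the fungus itself was not tested.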

How the results depend on the processing

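Root libraries held fewer fungal reads, which limits the detection of weak genes there, and none of the alternatives can separate condition from extraction method. With total gene reads 2963 genes were higher and 2662 lower. Over the scalings, filters, tools, thinning, total reads and the other added alternatives, the numbers of genes higher and lower in roots stayed within 1.5 times of 2960 and 2658, except that glmTreat against a fold of 2 gave 949 and 431. For changes of at least 5-fold, the exceptions were the 2-fold threshold (1921 higher, 1419 lower), the 10-fold threshold (358 and 97), glmTreat against a fold of 5 (306 and 63), limma-trend on log2(RPKM + 1) (427 and 128), where tool, scaling, filter and pseudocount differ together and the cause was not tested, and the filter of 5 CPM in 3 libraries (173 lower), which tested 11540 genes. Leaving out 1 library at a time gave 2052 to 2843 genes higher, 1611 to 2477 lower, 627 to 677 at least 5-fold higher and 241 to 329 at least 5-fold lower. The lowest counts of genes higher and lower came without mycelium replicate 1. The replicate block gave 2662 genes higher and 2454 lower, and 645 and 268 at least 5-fold, so the pairing by number changed no count by more than 1.5 times; 1 of the 3 root libraries correlated best with the mycelium library of its own number, and the numbers are not taken to pair the libraries. Genes detected in roots only and in mycelium only numbered 36 and 35 with a minimum of 1 read and 3 and 0 with a minimum of 50 reads, and thinning left 1 in mycelium only; leaving out 1 library gave 6 to 10 and 3 to 11. The difference in genes detected per library was -868 to -483 when 1 library was left out, -94 with a minimum of 1 read and -1122 with a minimum of 50 reads, and turned to 218 after thinning, which removes the difference in depth. The difference in the share of the 10 most abundant genes was -0.11 to 2.36 percentage points when 1 library was left out and 3.91 with counts divided by gene length. That of the 100 most abundant genes was -3.12 to -0.72 percentage points, and turned to 1.29 with counts divided by gene length; the cause was not tested. Leaving aside glmTreat, under which the named genes were not looked up, each of the 4 kept its direction and passed the threshold under every alternative that tested it. Their log2 fold changes were 7.90 to 17.47 (721864), 4.99 to 13.55 (546461), -8.81 to -6.74 (415105) and -7.02 to -4.55 (704713). The largest adjusted p-values were 2.97e-04 (721864), 0.00882 (546461), 0.00111 (415105) and 0.00871 (704713) by edgeR, DESeq2 or limma. The gene list tests (camera and fry) were not run, because no list could be formed, and the pseudocount alternatives were not run, because they applied only to tables without counts.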

Other observations

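In this part, the 3 other scalings and the thinned counts were set beforehand, but their use as tests of an explanation was chosen after the results were seen, as were the fit without the 10 most abundant genes, the balance shift, the share by quartile, the tests of the length trend and the splits of the libraries. The lists of the most abundant genes overlapped in part between the conditions. Of the 100 most abundant genes of mycelium and of roots, 42 were common to both lists, and of the 10 most abundant, 2 were. Among the 100 genes of highest mean abundance over all 6 libraries, 17 rose in roots, 44 fell and 39 did not pass the test (edgeR's quasi-likelihood test over all tested genes, adjusted p under 0.05); 9 rose and 12 fell by at least 5-fold.

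Some genes varied widely between replicates. More than 8-fold between the highest and lowest replicate were 27 of 9786 genes with a mean of at least 10 CPM in mycelium and 56 of 10054 in roots. In mycelium, 17 of the 27 were lowest in replicate 3, and in roots 33 of the 56 were lowest in replicate 2 and 21 in replicate 3. The third most abundant gene of mycelium was among the uneven ones, at 9941, 13390 and 948 CPM in replicates 1 to 3.

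Root replicate 3 showed the largest change in both directions. Genes at least 5-fold higher in roots had a median log2 change against the mean of mycelium of 3.38 in replicate 3 and 3.11 and 3.12 in replicates 1 and 2, and those at least 5-fold lower had -3.16 against -2.77 and -2.77. The most abundant gene of roots had 1228106, 1011732 and 1200674 unique reads in root replicates 1 to 3, and the second 298676, 273526 and 289473, while the library totals were 32853402, 33420275 and 17465257 reads.

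The excess of increases among changes of at least 5-fold (72.0%) was weighed against scaling, depth and foreign reads. Over 3 other scalings and a fit without the 10 most abundant genes, the share of increases was at least 70.8%, and with all libraries at the depth of the shallowest it was 72.5%, so neither the scalings run nor depth gave the excess. Those scalings moved the median log2 fold change by -0.03 to 0.10, while a shift of 0.47 would even out the 5-fold calls, and an error of that size in all of them is not excluded. Plant reads that match fungal gene models would add to the root counts of those genes, and their effect on the balance was not tested. The excess was also present in the most abundant quartile (68.3% increases), but libraries of uninoculated roots were not analysed here, and without them plant reads cannot be told apart from fungal induction in the roots, which remains open and untested.

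The trend of lower values in long genes was weighed against the extraction methods. The median rho over the 9 pairs of a root and a mycelium library was -0.10 and all 9 were negative, but pairs within a condition reached 0.14 in absolute size. Extraction chemistry and condition coincide, so a length bias of the extraction or library protocol cannot be told apart from a change in the fungus. The trend did not make the calls: with it removed, 89.3% of the 5618 called genes remained called in the same direction.

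For both counts of changed genes, 1 of the 10 splits of the 6 libraries into 3 and 3 gave a result as large, the real one. The real split called 5618 genes, and 931 of at least 5-fold, and the highest of the other 9 called 0 by edgeR's quasi-likelihood test (85 to 413 genes at an unadjusted p under 0.05). With 10 splits the share cannot fall under 0.05. Each of the other splits put libraries of both conditions in both groups, so the difference between conditions entered the spread within groups. Their unadjusted counts lay below the 731 genes of the simulation with no gene changed. The splits therefore cannot show how many genes would be called by chance.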
